A study of Homo sapiens with 22 samples.

How the data were processed

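RNA-seq of HEK293T cells covered 12 libraries in 6 groups of 2, and 10 further libraries of PAR-CLIP and PAR-CLIP with m6A immunoprecipitation were not analysed here. Groups were taken from the sample titles. Nothing in the labels says whether the 2 libraries of a group came from separate cultures. Per the labels' protocols, the RNA-seq libraries were stranded mRNA libraries. The submitters' processing notes name Trimmomatic, Bowtie 1.0.0, TopHat 1.1.4, Cufflinks, Cuffdiff and the hg19 build, with no role or order, and the sample descriptions name DEXSeq for the exon table. The values are log2 ratios of control over knockdown per exonic bin, which the authors computed and deposited, per the file headers. Their normalization, the DEXSeq version, the rule for listing a bin and any threshold are not given in the sources used here. Gene models have names of the AceView form, and names joined by "and" mark models that span several genes.

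The sign of the deposited log2 values was turned, so that a positive change is higher usage in the knockdown. Coordinates were used as deposited, in hg19 and counted from 1 with both ends included. Exon usage is relative to the rest of the gene model, so a change in 1 bin moves the value of the others. No counts were used here, so the depth per library and the precision of each bin are unknown.

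The tests fixed before the data were examined assumed a p-value per exon. With none used here, several choices were made after the table was examined. A bin was called if it was listed with a change other than 0, and for HNRNPG if KD1 and KD2 lay on the same side. A gene model took the median of its called bins in tests of direction, in place of the exon with the smallest p, and the longest bin was an alternative. Correlations used the median of all bins, with the mean of KD1 and KD2 for HNRNPG. HNRNPG bins were ranked by the smaller of KD1 and KD2. Sizes of 0.5 and 1 were alternatives for calls and directions, and were applied to overlaps of 2 knockdowns only after the table was examined.

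Direction was tested over gene models with an exact two-sided binomial test, with exact Clopper-Pearson intervals at 95% for the shares of gene models. Agreement in direction was tested with Fisher's exact test over gene models, in place of the planned permutation of signs. Correlations had permutation tests with 100000 resamples, two-sided, and intervals from 10000 bootstrap draws over gene models. Bin length was tested by permutation with 100000 resamples. Benjamini-Hochberg adjustment ran over 3 knockdowns, 3 pairs or 19 gene lists. Gene lists were fixed before the data were examined, and a joined model belonged to a list if any of its genes did. Of 780 symbols in the models, 676 were current symbols and 104 were not matched and were used as written.

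Named bins followed a rule fixed before the data were examined, with size in place of p. It took the 10 highest and 10 lowest per knockdown in single-gene models, 1 bin per model and side. Up to 4 per described list were added. The 10 bins with the largest median size among those on one side in all knockdowns were also taken, with 1 bin per single-gene model. Some were left out for length.

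The tests were tested on simulated data with the real 636 gene models. With no effect, the direction test passed 0.05 in 3% of 200 simulated datasets, and the agreement test in 3%. With 0.6 of the models lower, the direction test passed in 100%, and with a correlation of 0.3 the agreement test passed in 99.5%. These datasets took gene models as independent, with no shared controls and no rule that KD1 and KD2 agree. They do not check the agreement test for METTL3 and METTL14, which shared control libraries. Shared controls were simulated with 2 libraries per group and equal spread, and for overlaps the simulated values were cut at the observed share of bins. Alternatives covered minimum sizes, bins of at least 20 bp, joined models, single knockdowns, bins beyond 5 in size and other units of counting. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.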

Results

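HEK293T cells, a line derived from human embryonic kidney, were profiled in 22 libraries. RNA-seq made up 12 of them, in 6 groups of 2: controls of the HNRNPG series with knockdowns KD1 and KD2 of HNRNPG, and controls of the METTL series with knockdown of METTL3 and of METTL14. HNRNPG (gene RBMX) is a nuclear RNA-binding protein that takes part in splicing, and METTL3 and METTL14 form the enzyme complex that writes N6-methyladenosine (m6A) on RNA. The other 10 libraries were crosslinking experiments (PAR-CLIP, which sequences RNA crosslinked to a protein) for HNRNPG, 4 of them with or without an added m6A immunoprecipitation, and they were not analysed here. The values examined were the authors' comparisons of exon usage in genes with listed m6A sites, one value per exonic bin and knockdown. An exonic bin is a stretch of exon cut at every exon boundary of the gene model. No value per library, error or p-value was used here, so the depth behind each bin is unknown and no bin has a replicate check. Levels of RBMX, METTL3 and METTL14 themselves were not analysed here, so the knockdowns were not checked.

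The table held 2635 exonic bins in 636 gene models on 22 chromosomes, with a median of 2 bins per model and a median bin length of 157 bp. Of the models, 126 joined several genes under one name, and these held 1029 of the bins (39.1%). The models carried 1445 distinct m6A sites, with a median of 2 per model. A listed site lay inside 96 bins of 85 models, and the median distance from a bin to the nearest listed site of its model was 8545 bp. All changes below are log2 of knockdown over control, so a negative value is lower usage in the knockdown. Coordinates are hg19, and coding or untranslated status of the bins was not analysed here. How bins came to be listed is not given in the sources used here, and every listed bin with a change was counted as called.

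The first comparison asked which exons changed usage in HNRNPG knockdown. Ranked by the smaller change of KD1 and KD2 among single-gene models, the largest drop in usage belonged to a bin of RPL34, a protein of the large ribosomal subunit. In the authors' deposited table this bin (exon bin 16, chromosome 4, 109543361 to 109543670, 310 bp) had -2.19 in KD1 and -2.78 in KD2. Exon bin 27 of SETMAR, a fusion of a histone methyltransferase and a transposase (chromosome 3, 4359878 to 4363178), followed in the authors' deposited table with -1.89 and -2.02. PSMB7, a proteasome subunit, had -1.30 and -2.14 in exon bin 5 (chromosome 9, 127118493 to 127119042) in the authors' deposited table. Values below -1 in both knockdowns were also listed in the authors' deposited table for ARFIP2 exon bin 20 (-1.23 and -1.88), SRRT exon bin 62 (-1.30 and -1.19), DDB2 exon bin 58 (-1.18 and -1.05) and NXN exon bin 9 (-1.02 and -1.17). The SRRT bin was 1 bp long. With PKP4 exon bin 75, also below -1 in both, ZNF664 exon bin 56 (-2.02 and -0.99) and MRPS11 exon bin 10 (-0.99 and -1.03) completed the 10 lowest in the authors' deposited table.

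On the other side, the highest values shared by KD1 and KD2 in single-gene models belonged to FDXR, the mitochondrial ferredoxin reductase, and BSG, the membrane glycoprotein basigin. FDXR exon bin 16 (chromosome 17, 72860190 to 72860269) had 1.20 and 1.03 in the authors' deposited table. BSG exon bin 5 (chromosome 19, 572532 to 572569) had 1.01 and 1.58 in the authors' deposited table. Next in the authors' deposited table were ZNF655 exon bin 66 (1.42 and 0.95), a bin of 3 bp, LCORL exon bin 5 (0.97 and 0.92) and PRPF8 exon bin 48 (1.55 and 0.92). PRPF8 is the central protein of the spliceosome. LDHA, which interconverts pyruvate and lactate, had 1.00 and 0.91 in exon bin 17, and FZR1, an activator of the anaphase-promoting complex, had 0.83 and 1.42 in exon bin 7 in the authors' deposited table. The last of the 10 highest in the authors' deposited table were C12orf35 exon bin 8 (0.81 and 1.28), GLUL exon bin 44 (0.79 and 0.81) and IMMP1L exon bin 29 (0.79 and 0.97).

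KD1 and KD2 lay on the same side of 0 for 1968 of the 2635 bins. Usage was higher in 840 of these and lower in 1128, a higher share of 42.7%. Counted by gene model, with the median of its bins, 211 were higher and 328 lower, a higher share of 39.1% (95% exact Clopper-Pearson interval 35.0 to 43.4%; exact two-sided binomial p = 5.29e-07, adjusted over 3 knockdowns p = 1.59e-06). At a change of at least 0.5 in both, the bin share was 42.6% but the exact p over models was 0.0594, and at 1 these were 25% and 0.0768. These p-values, and those for the METTL knockdowns below, treat gene models as units and carry nothing on the spread between cultures. They also take values as centred at 0 and the listing as neutral to direction, and neither is known here. The median over bins was -0.037 in KD1, -0.064 in KD2, -0.039 in METTL3 and -0.043 in METTL14. KD1 and KD2 shared their control libraries. Their changes correlated with r = 0.542 across gene models (95% bootstrap interval 0.479 to 0.636) and r = 0.462 across bins. Simulated knockdowns without any effect gave r = 0.504, inside that interval and above the value across bins. In that simulation 66.9% of values agreed in direction, so much of the agreement between KD1 and KD2 could come from the shared controls. The median absolute difference between KD1 and KD2 was 0.19, close to the median size of the changes themselves, which was 0.19 in KD1 and 0.26 in KD2.

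The METTL3 comparison asked which exons changed in knockdown of the catalytic subunit of the m6A-writing complex. Its highest value in single-gene models belonged to RALGAPA1, part of a complex that restrains Ral GTPases. In the authors' deposited table RALGAPA1 exon bin 14 (chromosome 14, 36018316 to 36018379) had 2.58 and another bin of the gene, exon bin 60 (36211574 to 36211723), had -6.90. RAN, the GTPase of nuclear transport, had 2.35 in exon bin 17, RPL28 had 1.81 in exon bin 28 and FZR1 had 1.65 in exon bin 7 in the authors' deposited table. PCNP exon bin 29 (1.54), FDXR exon bin 16 (1.45), PPM1G exon bin 7 (1.40), C11orf59 exon bin 2 (1.38), MAPK9 exon bin 14 (1.35) and ZNF655 exon bin 66 (1.34) completed the 10 highest of such models in the authors' deposited table. The C11orf59 bin held a listed m6A site. Very low METTL3 values of single-gene models in the authors' deposited table belonged to BRP44L exon bin 19 (-8.62, a bin of 4 bp), NXN exon bin 9 (-6.76), ARFIP2 exon bin 20 (-6.13) and TXNL4A exon bin 18 (-5.75). In METTL14 knockdown the authors' deposited table gave these 4 bins -1.46, -0.91, -0.48 and -0.29. The rest of the 10 lowest METTL3 values of such models in the authors' deposited table were NUDT5 exon bin 26 (-2.53), TAF15 exon bin 16 (-2.37), TOX4 exon bin 32 (-2.34), NUCKS1 exon bin 6 (-2.31) and MFF exon bin 51 (-2.13).

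Usage in METTL3 knockdown was higher in 1228 bins and lower in 1406, a higher share of 46.6%. By gene model, 284 were higher and 350 lower, a higher share of 44.8% (95% exact interval 40.9 to 48.8%; exact binomial p = 0.00978, adjusted p = 0.00978). Without the joined gene models the bin share was nearly the same, 46.8%, and the exact p over the fewer models was 0.0626. Among the 590 bins with a change of at least 0.5, 389 were lower (65.9%).

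The METTL14 comparison asked the same of the partner subunit. PPM1G, a protein phosphatase that acts on splicing factors, had its highest value in single-gene models, 1.90 in exon bin 7 (chromosome 2, 27605096 to 27605342) in the authors' deposited table. MBD5 exon bin 5 (1.83), MPRIP exon bin 30 (1.53), HNRNPR exon bin 16 (1.51), MAEA exon bin 13 (1.45), RALGAPA1 exon bin 14 (1.34), COPS8 exon bin 36 (1.26), IMMP1L exon bin 29 (1.25), YWHAE exon bin 27 (1.20) and SPTLC1 exon bin 31 (1.20) followed as the rest of the 10 highest in the authors' deposited table. The lowest in single-gene models was PCNP exon bin 29, a bin of 3 bp at -1.95 in the authors' deposited table, which stood at 1.54 in METTL3 knockdown. TAF15 exon bin 16 (-1.87), NDUFS8 exon bin 33 (-1.86), RALGAPA1 exon bin 60 (-1.79), MFF exon bin 51 (-1.77) and BRP44L exon bin 19 (-1.46) came next in the authors' deposited table. TAF15 is an RNA-binding protein of the FET family, and MFF recruits the mitochondrial fission machinery. BCAT2 exon bin 43 (-1.45), M6PR exon bin 2 (-1.44), RPL34 exon bin 16 (-1.31) and ATP5F1 exon bin 26 (-1.25) were the last of the 10 lowest of such models in the authors' deposited table. The BCAT2 bin was 14 bp long and the M6PR bin 2 bp.

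Usage in METTL14 knockdown was higher in 1143 bins and lower in 1482, a higher share of 43.5%. By gene model, 260 were higher and 373 lower, a higher share of 41.1% (95% exact interval 37.2 to 45.0%; exact binomial p = 8.09e-06, adjusted p = 1.21e-05). Of the 422 bins with a change of at least 0.5, 278 were lower (65.9%). At a change of at least 1 the share of bins higher was 33.8% with an exact p over models of 0.233, so the direction was no longer past the threshold.

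The study asked whether HNRNPG and the m6A writers act on the same exons. Bins on one side in every knockdown included BSG exon bin 5, FZR1 exon bin 7 and ZNF655 exon bin 66, all higher. RALGAPA1 exon bin 14 was higher too, with 0.64, 1.11, 2.58 and 1.34 in KD1, KD2, METTL3 and METTL14 in the authors' deposited table. In the authors' deposited table BSG had 1.22 in METTL3 and 0.92 in METTL14 knockdown, and FZR1 had 1.65 and 0.73. Lower in every knockdown were RPL34, ARFIP2, NUDT5, BRP44L, SETMAR, NXN and RALGAPA1 exon bin 60. Their sizes differed between knockdowns, and SETMAR had -0.31 and -0.20 in the METTL knockdowns in the authors' deposited table against -1.89 and -2.02 in the HNRNPG knockdowns. RALGAPA1 exon bin 60 had -0.82, -7.37, -6.90 and -1.79 in KD1, KD2, METTL3 and METTL14 in the authors' deposited table.

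**Figure D1:**
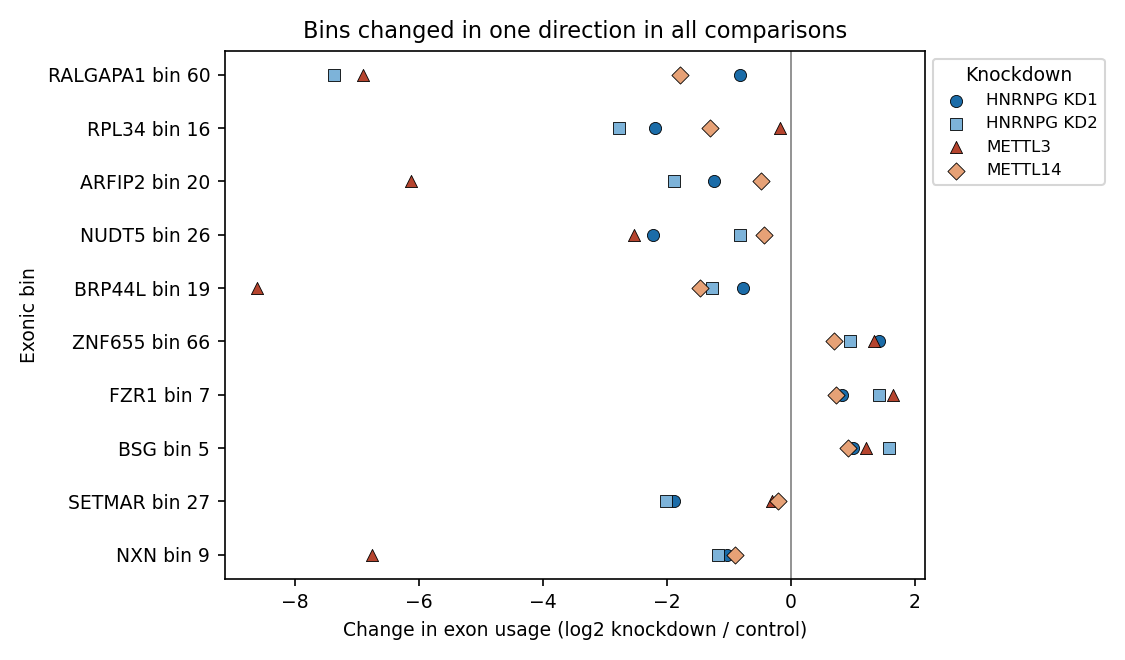
Change in usage (log2 knockdown over control, x axis) of 10 exonic bins on one side of 0 in every comparison. They have the largest median size among single-gene models, with 1 bin per model, so RALGAPA1 exon bin 14 is left out. Each marker is one knockdown. BSG, FZR1 and ZNF655 lie above 0, and the other 7 lie below, with isolated METTL3 values as low as -8.62 for BRP44L. RALGAPA1 exon bin 60 also has -7.37 in KD2, where KD1 has -0.82.

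Only 1 METTL3 value and 10 METTL14 values were 0, so nearly every bin was called in both METTL knockdowns. Counts of bins called in 2 or 3 knockdowns thus do not measure shared change. HNRNPG and METTL3 knockdown had 1967 bins called in both, and 1405 of them (71.4%) changed in the same direction. By gene model, 368 of 537 agreed in direction (68.5%), where the margins alone gave 51.4% (Fisher's exact test, two-sided, p = 2.25e-16, adjusted over 3 pairs p = 2.25e-16). HNRNPG and METTL14 had 1959 bins in both and 1399 (71.4%) in the same direction, and 373 of 536 models agreed (69.6% against 51.8%, Fisher's exact p = 1.11e-17, adjusted p = 1.66e-17). Across the 636 gene models the changes correlated with Pearson r = 0.316 for HNRNPG and METTL3 (Spearman rho = 0.348) and r = 0.402 for HNRNPG and METTL14 (rho = 0.403). Each of these had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1e-05. Without the 2 models farthest from the HNRNPG median, r was 0.389 and 0.407. With KD1 and KD2 taken singly, a choice made after the table was examined, r was 0.222 and 0.336 with METTL3 and 0.268 and 0.432 with METTL14. The difference between KD2 and KD1 was 0.113 for METTL3 (95% bootstrap interval over gene models -0.0490 to 0.253) and 0.163 for METTL14 (0.0551 to 0.270), and its cause was not tested. The HNRNPG and METTL series had separate control libraries. Gene models are not independent replicates, and the unknown rule for listing bins could affect agreement between knockdowns.

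**Figure D2:**
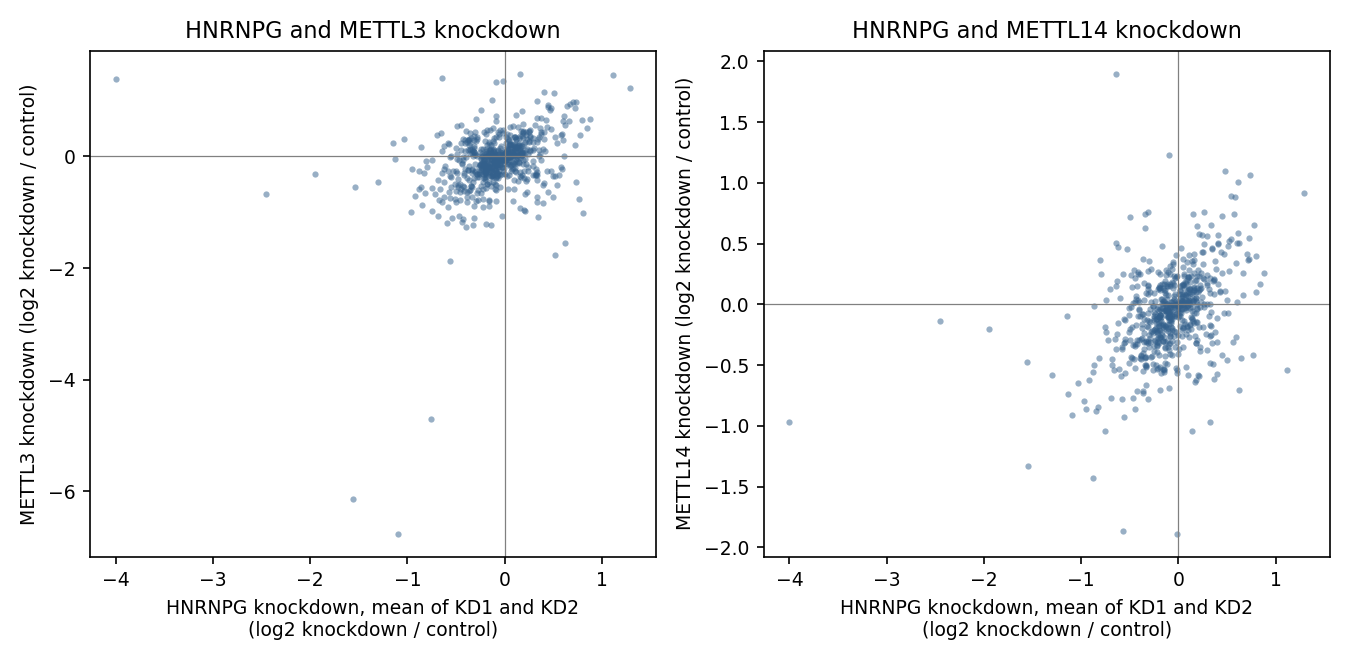
Median change per gene model (log2 knockdown over control) in HNRNPG knockdown, as the mean of KD1 and KD2 (x axis), against METTL3 (left) and METTL14 knockdown (right); each point is 1 of 636 models, and the y axes differ in range. Both clouds slope upward, with r = 0.316 and r = 0.402.

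METTL3 and METTL14 knockdown shared their control libraries. They had 2624 bins in both, 1706 (65.0%) in the same direction, and 437 of 631 models agreed (69.3% against 50.9% from the margins, Fisher's exact p = 2.93e-21, adjusted p = 8.78e-21). Simulated knockdowns without any effect, set against the same 2 controls, agreed in direction for 66.9% of values with r = 0.504. The observed correlation was r = 0.336 (rho = 0.390, both permutation p = 1e-05, adjusted p = 1e-05; r = 0.347 without the 2 farthest models), with a covariance of 0.0725. The bin share and the correlation lay below the simulated values, and the gene-model share lay above, with an exact interval (65.5 to 72.8%) that spans 66.9%. A simulated covariance needs the spread between libraries, which was not used here, and without values per library the controls could not be split.

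At a change of at least 0.5, a size chosen after the table was examined, HNRNPG and METTL3 had 105 bins in the same direction, against 22.0 for independent lists. HNRNPG and METTL14 had 79 against 15.8, and METTL3 and METTL14 had 136 against 52.0. These baselines take bins as independent, while bins of one model can move together and the precision of each bin is unknown. By gene model, in any direction, HNRNPG and METTL3 both had a bin of that size in 90 models, against 51.5 for independent lists. For HNRNPG and METTL14 these were 72 and 38.7. The number of bins per model was not allowed for, so the size of the excess stays open. The value of 52.0 leaves out the shared controls, and simulated METTL knockdowns without any effect, called at the observed share of bins, gave 158. Of the bins that reached 0.5 in both METTL knockdowns, 79.5% agreed in direction, against 97.9% in that simulation. With equal spread in all groups, that simulation had r = 0.504. This lies above the bootstrap interval of 0.234 to 0.431 around the observed r of 0.336 across gene models. Its count of 158 is thus no sound baseline for these data. Whether part or all of the excess over 52.0 comes from the shared controls cannot be decided here. All 3 knockdowns were called in 1958 bins, nearly all that were called for HNRNPG. Of these, 1070 (54.6%) changed in one direction, 439 higher and 631 lower. By gene model 267 of 636 (42.0%) had all 4 medians on one side. Shuffling the METTL pair against the HNRNPG pair, which keeps the shared controls of each, gave a mean of 174 models and at most 211 in 10000 shuffles (Fisher's exact p = 3.55e-25).

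Groups of splicing factors were small, and none passed the adjusted threshold. Models of hnRNPs and other RNA-binding splicing regulators were higher in 9 and lower in 6 in HNRNPG knockdown (Fisher's exact p = 0.111, adjusted over 19 lists p = 0.513). Without joined models these numbered 9 and 3 (Fisher's exact p = 0.0130, adjusted p = 0.246). The hnRNP group was higher in 8 and lower in 12 in each METTL knockdown. In the authors' deposited table HNRNPA2B1 exon bin 1 (chromosome 7, 26228802 to 26229547) had 0.34, 1.43, 0.82 and 1.05 in KD1, KD2, METTL3 and METTL14. HNRNPR exon bin 16 had -1.75, -0.38, 0.74 and 1.51 in that order in the authors' deposited table. The median over all bins of the HNRNPR model was 0.06 in KD1 and 0.11 in KD2. SR proteins and related regulators had 1 model higher and 5 lower in HNRNPG knockdown, 4 and 4 in METTL3 and 3 and 5 in METTL14. SRSF10 exon bin 13, of a splicing repressor, had -0.40, -0.16, -0.36 and -0.39 in that order in the authors' deposited table, and ACIN1 exon bin 1 had -0.56, -1.70, 0.89 and 0.37. The ACIN1 bin was 8 bp long, and the median over all bins of its model was -0.23 in METTL3 and -0.35 in METTL14. Core spliceosome components had 1 model higher and 5 lower in HNRNPG knockdown and 4 and 4 in each METTL knockdown. The m6A writers, erasers and readers were covered by 2 models, HNRNPA2B1 and HNRNPC, both higher in HNRNPG knockdown and split 1 and 1 in each METTL knockdown.

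In METTL3 knockdown all 7 models of DNA repair genes were lower, with a median of -0.43 (Fisher's exact p = 0.0187, adjusted over 19 lists p = 0.355). DDB2 exon bin 48 had -1.57, FANCI exon bin 83 had -0.95 and XRCC3 exon bin 24 had -1.76 there in the authors' deposited table, while FANCA exon bin 62 had 0.69. In METTL14 knockdown the authors' deposited table gave these bins 0.002, -0.08, -0.07 and -0.12 in that order. DNA repair models were higher in 3 and lower in 4 in METTL14 knockdown (median -0.0115), and 2 and 5 in HNRNPG knockdown. Translation initiation and elongation factors were higher in 8 of 10 models in METTL14 knockdown (Fisher's exact p = 0.0189, adjusted p = 0.359) and lower in 8 of 10 in HNRNPG knockdown (adjusted p = 0.782). In METTL3 knockdown 4 models of these factors were higher and 5 lower. No list of the 19 passed the adjusted threshold in any knockdown by Fisher's exact test, and 2 of 57 tests had an unadjusted p under 0.05.

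Other lists were split as follows in HNRNPG, METTL3 and METTL14 knockdown. Zinc finger models were higher in 7, 12 and 8 and lower in 10, 8 and 12. Membrane trafficking models were higher in 1, 5 and 6 and lower in 8, 7 and 6, with DNM1 exon bin 46 at -0.77, -0.90, -1.29 and -1.01 and EPS15L1 exon bin 18 at 0.13, 0.71, 0.85 and 0.67 in the authors' deposited table. Chromatin models were higher in 5, 5 and 5 and lower in 7, 7 and 7. Cytoskeleton and adhesion models were higher in 5, 6 and 5 and lower in 4, 3 and 4, with ENAH exon bin 28, of an actin regulator, at 0.74, 1.01, 1.25 and 0.99 and MYH10 exon bin 7 at -0.92, -0.20, -1.26 and -0.73 in the authors' deposited table. Genes with textbook alternative exons were higher in 2, 3 and 3 and lower in 4, 5 and 5. Polyadenylation factors were higher in 0, 1 and 2 and lower in 5, 4 and 3. Ubiquitin ligases and deubiquitinases were higher in 0, 1 and 1 and lower in 5, 4 and 4. MAPK, PI3K and mTOR signalling models were higher in 1, 3 and 1 and lower in 3, 2 and 4. Cell cycle models were higher in 2, 4 and 2 and lower in 2, 1 and 3, and apoptosis models were higher in 2, 2 and 2 and lower in 0, 1 and 1. Decay factors were higher in 1, 2 and 1 and lower in 1, 0 and 1, as were export and nonsense-mediated decay factors. Models of WNT and related signalling were higher in 1, 1 and 0 and lower in 1, 1 and 2.

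Bin length differed by direction in HNRNPG knockdown. Models that were higher had a median bin length of 198 bp against 426 bp in those that were lower (permutation p = 0.00046, adjusted p = 0.00138). Over all bins the difference in medians was smaller, at -81.5 bp, and was not tested in a way that allows for bins of the same model. In METTL3 knockdown the medians were 368 and 308 bp (permutation p = 0.439, adjusted p = 0.439), and in METTL14 knockdown 301 and 400 bp (permutation p = 0.141, adjusted p = 0.212). At changes of at least 0.5 the HNRNPG difference was -159 bp with a permutation p of 0.0683.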

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

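Of the tests in this part, the one on correlation with HNRNPG was chosen after its values were seen. METTL3 knockdown had more large changes than METTL14 knockdown against the same controls. A change of at least 0.5 was listed for 22.4% of bins in METTL3 and 16.0% in METTL14 knockdown, a mean difference over gene models of 7.54 percentage points (permutation p = 3e-05 by swapping the knockdowns within models). More noise in the METTL3 arm may account for this, and would lower its correlation with HNRNPG. The Spearman correlation was 0.0543 higher for METTL14, with a bootstrap interval from -0.0389 to 0.147. Large changes were also compared with HNRNPG in bins where KD1 and KD2 lay on the same side, 473 for METTL3 and 317 for METTL14. Large changes in bins where KD1 and KD2 disagreed were left out. The share on the HNRNPG side was 83.1% for METTL3 and 83.9% for METTL14, a difference of 0.825 points with an interval from -7.92 to 8.97. Both intervals span 0, so noise and a larger effect of METTL3 knockdown cannot be told apart without values per library.

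HNRNPG KD2 had more large changes than KD1, with 21.7% against 15.0% of bins, a mean difference over gene models of 6.68 percentage points (permutation p = 5e-05). The p-values of these differences compare gene models within the pooled comparisons, not cultures.

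In 2 bins both HNRNPG knockdowns were at least 0.5 higher and both METTL knockdowns at least 0.5 lower, against 43 bins with all 4 values on one side at that size. The difference was not tested. In the authors' deposited table PRPF8 exon bin 48 (chromosome 17, 1576862 to 1577039) had 1.55, 0.92, -1.99 and -0.63 in KD1, KD2, METTL3 and METTL14. TTC15 exon bin 37, a bin of 3 bp chosen after its values were seen, had 0.73, 0.61, -1.29 and -0.63 in the authors' deposited table. With no minimum size, 339 gene models had the KD1 and KD2 medians on one side and the METTL3 and METTL14 medians on one side. Of these, 267 (78.8%) had all 4 on the same side, and in the rest the HNRNPG pair lay opposite to the METTL pair. Among bins, PPM1G exon bin 7 was opposite too, with -0.91, -0.37, 1.40 and 1.90 in that order in the authors' deposited table. So was TAF15 exon bin 16, with 0.34, 1.65, -2.37 and -1.87 in the authors' deposited table.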

How the results depend on the processing

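Of 100 alternatives, 61 kept the direction and side of the threshold or stayed within 1.5 times the count, 30 counts moved further, 7 tests fell short of the threshold and 2 reversed. Chosen after seeing the data were the longest bin per model, single HNRNPG knockdowns, leaving out bins beyond 5 in size for direction shares, sizes for overlaps of 2 knockdowns, leaving out joined models for overlaps, agreement and correlation, and short bins in agreement and correlation. All correlations kept their sign and a permutation p under 0.05 in the alternatives run, between 0.222 (HNRNPG KD1 alone with METTL3) and 0.432. No paired analysis was possible because the values come from comparisons with no value per library, and leaving out a replicate, a stricter p and another normalization were not run for that reason. Overlap by 1 bp equals identity here and was not run.

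At a size of at least 0.5, called bins numbered 188, 590 and 422 for HNRNPG, METTL3 and METTL14, and at least 1 left 20, 151 and 68. Without joined models they numbered 1256, 1606 and 1598, and counted as gene models 556, 636 and 635. Bins called in both for HNRNPG and METTL3, HNRNPG and METTL14, and METTL3 and METTL14 numbered 117, 88 and 171 at 0.5, 7, 3 and 26 at 1, 1256, 1249 and 1598 without joined models, and 556, 555 and 635 as gene models. Called in all 3 were 52 bins at 0.5, 1249 without joined models and 555 gene models, and in one direction 43, 699 and 362. These counts fall by construction.

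The share higher in HNRNPG knockdown was 42.6% at 0.5 (exact p = 0.0594) and 25% at 1 (exact p = 0.0768), in METTL3 46.8% without joined models (exact p = 0.0626), and in METTL14 33.8% at 1 (exact p = 0.233). Same-direction shares at 1 were 85.7% for HNRNPG and METTL3 (exact p = 0.4) and 100% for HNRNPG and METTL14 (exact p = 0.333), with few models left. For METTL3 and METTL14 the share at 1 was 61.5% (16 of 26 bins, Fisher's exact p over models = 0.0014). Simulated METTL knockdowns without any effect gave 100% at that size. The HNRNPG length difference was -159 bp at 0.5. The METTL3 length difference, 59.8 bp, reversed to -15 bp over all bins and -142 bp at 0.5, with permutation p of 0.247 (which treats bins as independent) and 0.0553; the cause was not tested.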

Other observations

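In this part, the tests on ribosomal protein genes, on values beyond 5 and on m6A sites without matching by model were chosen after the data were seen. Models of ribosomal protein genes were in no fixed list, and RPL7L1 was counted with them. Some joined other genes, such as ARL6IP1andRPS15A, RPS10andNUDT3 and RPL11andTCEB3. The 19 models in the table also included RPL34, RPL24, RPS14 and RPS6. In METTL3 knockdown 4 were higher and 15 lower, in METTL14 knockdown 4 and 15, and in HNRNPG knockdown 3 and 13 of those with called bins. The hypothesis that they are lower more often than other models gave differences of 24.5, 20.6 and 21.0 percentage points (Fisher's exact p = 0.0368, 0.0964 and 0.119, adjusted over 3 p = 0.110, 0.119 and 0.119). With all bins in the medians instead of called bins, an earlier choice, the exact p was 0.0368, 0.0489 and 0.0335 (adjusted p = 0.0489 for each). The result thus rests on that choice and stays open.

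A further hypothesis, set before its values were seen, was that bins holding a listed m6A site are more often lower than other bins of the same model. The mean difference within models was -5.78 percentage points in HNRNPG knockdown (95% bootstrap interval -20.4 to 8.66, 61 models), 4.92 in METTL3 (-6.30 to 16.1, 80 models) and 5.98 in METTL14 (-6.11 to 17.6, 80 models). Sign-flip permutation p was 0.443, 0.400 and 0.334 (adjusted p = 0.443 for each), so no difference within models was shown, and the intervals leave room for differences of over 10 points. Over all bins, without matching by model, the share lower with and without a site was 53.3% and 57.5% in HNRNPG knockdown, 64.6% and 53.0% in METTL3, and 66.3% and 56.1% in METTL14. These differences were -4.14 points (bootstrap interval over gene models -16.1 to 8.03), 11.6 (1.095 to 21.9) and 10.2 (-0.114 to 20.4). The METTL3 interval lies above 0 with no adjustment for the 3 knockdowns, but this comparison also takes in differences between models, so the hypothesis stays open. The number of sites per model had a Spearman correlation of 0.00259 with the size of the HNRNPG change (permutation p = 0.948) and 0.0188 with that of the METTL changes (permutation p = 0.637). For the median distance to the nearest site the correlations were 0.0580 (permutation p = 0.143) and -0.0301 (permutation p = 0.449).

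Values beyond 5 in size numbered 17, in 15 bins, while 1 value lay between 3 and 5. For 15 of the 17, the other knockdown of the series stayed below 3. CTNNB1 exon bin 15 had -7.51 in KD2 and -0.28 in KD1 in the authors' deposited table. Few reads in short bins may be the cause. The mean log10 length of bins with such a value differed from that of other bins by -0.266, where the bootstrap interval (-0.568 to -0.000122) lies just below 0 but the permutation p is 0.160. Of 14 gene models with such a value, 13 were lower in the knockdown (92.9%, exact interval 66.1 to 99.8%), where loss of reads in any of the 6 groups alike would give 66.7% (exact binomial p = 0.0448). The interval spans that share while p lies just under 0.05, so chance loss cannot be told apart from a real drop without counts.

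Joined models held 39.1% of bins, and different regulation of the joined genes could look like exon usage. If so, a single split along the model would explain more of the variance in joined than in single-gene models. The excess over shuffled order had a median difference of -0.0794, joined minus single-gene models (bootstrap interval -0.165 to 0.0580, permutation p = 0.214) over 59 joined and 69 single-gene models, which decides nothing.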
